A study of Mus musculus with 20 samples.

How the data were processed

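RNA of mouse CD8 T cells carrying the OT-I receptor, a transgenic T cell receptor that recognises an ovalbumin peptide on the class I molecule H-2Kb, was measured on 20 Affymetrix oligonucleotide arrays. Per the labels' protocols, CD44-low CD8 cells were taken from lymph nodes by negative enrichment. They were cultured with IL-2 on microspheres carrying the peptide complex and the costimulatory protein B7-1 (antigen and B7, written Ag-B7). IL-12, type I interferon (IFNa/b) or trichostatin A (TSA, a histone deacetylase inhibitor) was added or left out. Labelled cRNA was prepared from 10 ug of total RNA, per the labels' protocols, and hybridised as 1 sample per array with 1 colour.

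The deposited values are intensity values, 1 MAS5 signal for each of 12488 probe sets on every array. MAS5 is named in the submitters' processing notes, and its version and scaling target are not given in the sources used here. The values lay between 0.195 and 243826 on a linear scale, and none was missing. Their mean over all probe sets after leaving out 2% at each end was 1000.46 to 1000.74 on the 20 arrays, so each deposited array had been scaled to a common mean. The median intensity still differed between arrays, from 232 to 507, and no further normalization was visible. Scaling to a common mean makes every difference relative to the total labelled RNA of an array and cannot show a change of the total.

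Gene names came from the annotation of the array's platform, in which 10833 probe sets had 1 gene symbol, 396 had several and 1193 were not listed; the other 66 were control probe sets. Names were compared with a current gene table by gene identifier for 10817 probe sets, and 0 symbols needed an update. Only probe sets with 1 symbol were named, for 8251 different genes. For the 2073 genes with several probe sets, the probe set with the highest mean log2 value over the 20 arrays stood for the gene, and the others were kept as a check. No genome build was used, so no coordinates are given. Probe sets of close relatives (granzymes, Ctla2, Slfn, Ifit, Mt, Klr, H2, histone and immunoglobulin genes, and the Isg15-like gene Gm9706) may not tell family members apart.

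Values were transformed as log2(value + 46.4), where the pseudocount was the median over the arrays of each array's 20th percentile. Fold changes are on this scale, which understates the change of dim genes. A gene was kept when its value exceeded its array's 40th percentile on at least 3 of the 13 replicated arrays, which left 6278 genes. The labels gave 11 groups and called the replicates biological. Naive cells (3 arrays), Ag-B7 at 48 h (4 arrays), Ag-B7 with IL-12 at 48 h (3 arrays) and Ag-B7 with IFNa/b at 48 h (3 arrays) were replicated, and the other 7 groups had 1 array each. The 13 replicated arrays were fitted together in limma 3.58.1 (R 4.3.3) with group means and moderated variances that followed the mean intensity. The fit had 9 residual degrees of freedom and 7.62 prior degrees of freedom, and the median residual SD was 0.372 on the log2 scale. Tests were two-sided with Benjamini-Hochberg adjustment over the 6278 genes, and genes were called at an adjusted p below 0.05. Errors given after ± are the standard errors of limma unless named SD. The number of arrays limits the precision of every value.

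Gene lists were fixed before the data were examined: 18 theme lists and 8 marker lists, with 459 of 572 genes on the array under a single symbol. The theme lists were cytotoxic effector molecules, cytokines and chemokines, cytokine receptors and JAK-STAT components, homing and adhesion receptors, costimulatory and inhibitory receptors, interferon-stimulated antiviral genes, MHC class I antigen presentation, IL-12 and STAT4 associated genes, lymphocyte fate transcription factors, naive T cell and quiescence genes, survival and apoptosis genes, cell cycle and DNA replication, glycolysis, ribosome biogenesis and MYC targets, amino acid transport and endoplasmic reticulum stress, chromatin modifiers, genes raised by histone deacetylase inhibitors, and immediate early and heat shock genes. The marker lists covered B cells, myeloid and dendritic cells, NK cells, CD4 and gamma-delta T cells, erythroid cells and platelets, stromal and endothelial cells, CD8 T cell identity and reference genes. Each theme list was tested with camera (limma), which compares its genes with all others, at a preset correlation of 0.01 and again with an estimated correlation, and with fry, adjusted over the 18 lists. The counts of called members are given over all genes and adjusted over the list alone.

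Named genes followed a rule also fixed before the data were examined. It took the 10 called genes with the largest rise and the 10 with the largest fall in each comparison, among those whose arrays did not overlap and whose brighter group was above the median gene. It added up to 4 called members of each theme list or, where none was called, the member with the largest difference, and genes chosen in advance for T cell function, some of which are not analysed here. For single arrays it took the 5 largest differences each way. Genes named outside the rule are said to be so.

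Groups with 1 array have no replicate check, so no p-value is given for them. Their 2-fold differences were counted among genes whose brighter value was above its array's median and set beside the same count between replicate arrays. The median of a list was ranked among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of those arrays. The IL-12 and IFNa/b effects share their control arrays, so their overlap was set beside 100 simulations of unchanged groups against the same controls and repeated with the 4 control arrays split.

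The replicate numbers of the labels were checked for pairing. The deviations of same-numbered Ag-B7 and IL-12 arrays at 48 h from their group means correlated at 0.280, 0.280 and 0.276. All were above the bound of 0.1, so these numbers were taken to pair the arrays. No other pair of replicated groups passed that bound at every number. The labels do not say what a number marks, and arrays of different numbers in other pairs of groups reached up to 0.348. The fit with the replicate number as a block is printed beside the IL-12 results where it changed them. For comparisons at 48 h that fit held the 48 h arrays alone, so it differs from the main fit in leaving out the naive arrays as well. No 2 arrays held the same values at more than 0.00923% of probe sets.

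The fit was tested on simulated data with 200 of 6278 genes changed, in 10 runs. For IL-12 against Ag-B7 it recovered 46.4% of genes changed by 1 on the log2 scale and 88.6% of those changed by 2, with 5.26% of calls false. For IFNa/b the values were 47.2%, 88.7% and 4.97%. For IL-12 against IFNa/b they were 38.7%, 85.6% and 6.05%. The simulated noise was independent between genes and unpaired. More genes were changed than the cytokine comparisons called here, which eases the adjusted threshold, so recovery in the data may be lower. The alternatives fixed before the data were examined were quantile normalization, median centring, a smaller pseudocount and 4 times the pseudocount, other filters, all probe sets, no intensity trend, only the arrays of the compared groups, a 2-fold minimum, the replicate block, each array left out in turn, other probe sets of named genes and the estimated correlation. Scaling on the spiked-in hybridization controls, fits of the 48 h arrays alone and the block within the IL-12 and Ag-B7 arrays alone were chosen after seeing the data, as were the marker counts without naive replicate 2 or 3 and the list medians of single arrays under other scalings. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.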

Results

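Transcript levels were measured in OT-I CD8 T cells before stimulation and after 24, 48 and 72 h in culture. Ag-B7 (antigen and B7-1, the first and second signals of T cell activation) was given alone or with a cytokine as the third signal, IL-12 or IFNa/b, and at 72 h also with TSA. The cultures also held IL-2, so Ag-B7 alone means without IL-12, IFNa/b or TSA. The design asked how naive cells, cells given Ag-B7 alone and cells given Ag-B7 with a cytokine differ over the first days, and how TSA compares with the cytokines. Naive cells had 3 arrays, Ag-B7 at 48 h had 4, and Ag-B7 with IL-12 or with IFNa/b at 48 h had 3 each. The other 7 groups had 1 array each and no replicate check. Replicate arrays of a stimulated group correlated at 0.948 to 0.966 across genes. Naive arrays correlated at 0.827 to 0.932, and the lowest mean correlation, 0.848, was that of naive replicate 2, whose ratio of 3' to 5' actin signal was 2.06. The ratio was 1.61 on naive replicate 3 and at most 1.15 on any stimulated array, so 2 of the 3 naive arrays stood above all stimulated ones.

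From the naive state to 48 h of Ag-B7, most of the cell cycle and glycolysis genes tested rose. No group was cultured without antigen and B7, so their effect cannot be told apart from that of IL-2 and of time in culture. Gzmb, the serine protease of cytotoxic granules, rose 53.8-fold (log2 difference 5.75 ± 0.27, n = 4 and 3, limma adjusted p = 7.6e-11). The mitotic kinase Cdk1 rose 48.9-fold, the DNA topoisomerase Top2a 42.9-fold, the proliferation marker Mki67 36.9-fold and the mitotic regulator Birc5 28.6-fold. Genes that fell were, among others, Il7r, the receptor chain for the survival cytokine IL-7 (log2 difference -3.74 ± 0.35), and Klf2, a transcription factor of quiescence and lymph node recirculation (-4.08 ± 0.45). The largest falls by the naming rule were those of Vps37b (-5.42 ± 0.38), a component of endosomal sorting, and of Cd7, a T cell surface protein (-5.23 ± 0.49).

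Costimulatory receptors of the tumour necrosis factor receptor family were among the risers, with Tnfrsf9 (4-1BB) at 4.74 ± 0.36 and Tnfrsf4 (OX40) at 3.73 ± 0.54 on the log2 scale. The inhibitory receptor Lag3 rose by 4.02 ± 0.43, the IL-2 receptor chain Il2ra 8.01-fold and the adhesion receptor Cd44 5.94-fold. The chemokines Ccl4 and Xcl1 rose 10.6-fold and 10.5-fold. Ifng, the gene of interferon-gamma, rose 4.65-fold (log2 difference 2.22 ± 0.49, limma adjusted p = 0.00111), and the IL-12 receptor chain Il12rb2 4.29-fold. The transcription factors Bhlhe40 (3.71 ± 0.46) and Irf8 (3.66 ± 0.37) rose, while Bcl3, a survival-linked cofactor of NF-kappaB, fell (-2.78 ± 0.50). Gzma, a second granule protease, fell (-2.46 ± 0.45). The pore-forming protein gene Prf1 had a log2 difference of -1.14 ± 0.37 (limma adjusted p = 0.0143), but its limma adjusted p was 0.0797 without naive replicate 1 and 0.0751 under quantile normalization. Stat4, which carries the IL-12 signal, differed by -0.16 ± 0.30, and the effector transcription factor Eomes by -0.74 ± 0.52, neither of them called. A dimmer probe set of the same gene had the opposite sign for Mki67, Tnfrsf9, Cd44, Hk2, Lta, Mthfd2 and Bad.

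Of 41 cell cycle and DNA replication genes, 35 rose and 0 fell, with a median log2 difference of 2.35, and the count was the same adjusted over the list alone. Of 16 glycolysis genes 14 rose and 1 fell, with the rises led by Tpi1 (18.2-fold), Pgam1 (10.6-fold), Hk2 (10.4-fold) and Pgk1 (8.38-fold), and 18 of 25 ribosome biogenesis and MYC target genes rose, including Myc itself (5.48-fold) and the spermidine synthase Srm (4.24-fold). Of 27 chromatin modifiers 16 rose and 3 fell, with the DNA methylation factor Uhrf1 (20.2-fold) and the histone methyltransferase Ezh2 (6.16-fold) among the risers. These 4 lists moved up under quantile normalization, median centring and spike-in scaling as well. Counts adjusted over the list alone were the same for these lists too. The preset camera test (limma) called all 4, with adjusted p = 1.44e-20 for cell cycle, 1.23e-07 for glycolysis, 2.51e-06 for ribosome biogenesis and 0.00237 for chromatin. With an estimated correlation only cell cycle was called (adjusted p = 0.00233 with an estimated correlation), and the others had adjusted p = 0.121, 0.149 and 0.181 with an estimated correlation. The fry test (limma) called all 4 higher (adjusted p = 1.61e-10, 5.76e-07, 1.64e-05 and 3.42e-05).

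Of 25 naive T cell and quiescence genes 21 fell and 0 rose, with a median of -1.90; 20 fell under quantile normalization and 15 under median centring, but under spike-in scaling 4 fell and 4 rose. Of 31 interferon-stimulated antiviral genes 21 fell and 1 rose, with a median of -1.32, which turned to 0.46 under spike-in scaling, where 12 rose and 2 fell. The transcription factor of interferon responses Irf7 fell by 4.64 on the log2 scale, Ifit3 by 3.73, Ifit1 by 2.91 and Usp18, a protease that removes the ubiquitin-like protein ISG15, by 2.89. Of 31 cytokine receptors and JAK-STAT components 15 fell and 4 rose, among the falling ones Il4ra (-2.82 ± 0.39) and Ifngr2 (-3.64 ± 0.40), with a median of -0.62 that turned to 0.02 under median centring and 1.16 under spike-in scaling, where 16 rose and 2 fell. Counts adjusted over the list alone were the same for these 3 lists. The preset camera test (limma) called these 3 lists lower relative to other genes (adjusted p = 6.2e-07, 0.000351 and 0.0300), and each call was lost, with adjusted p = 0.0879, 0.149 and 0.320 with an estimated correlation. The fry test (limma) called all 3 lower (adjusted p = 5.76e-07, 6.31e-06 and 6.69e-05). It does not compare a list with other genes, so it depends on the scaling of the arrays. Under spike-in scaling camera again placed the interferon-stimulated and receptor lists below other genes.

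The remaining 11 lists were not called by camera. The fry test (limma) called several of them, among others homing receptors lower (adjusted p = 3.53e-05) and costimulatory receptors higher (adjusted p = 8.94e-05). It did not call cytotoxic molecules, cytokines and chemokines or survival genes (fry adjusted p = 0.137, 0.585 and 0.0623). Immediate early and heat shock genes gave 9 falls and 3 rises among 19, with Fos (-4.27 ± 0.41) and Dusp1 (-3.13 ± 0.35) lower in stimulated cells. Homing and adhesion receptors gave 10 falls and 2 rises among 19, including S1pr1, which guides exit from lymph nodes (-2.59 ± 0.42), and the gut homing receptor Ccr9 (-2.88 ± 0.42), and turned to 9 rises and 1 fall under spike-in scaling. Members moved both ways among cytotoxic molecules (4 rose and 6 fell of 14, a median of -0.07 beside an upward camera direction), cytokines and chemokines (6 and 4 of 14, a median of -0.09 beside an upward camera direction), costimulatory and inhibitory receptors (9 and 3 of 18), MHC class I presentation (3 and 7 of 13), IL-12 and STAT4 associated genes (8 and 4 of 17), fate transcription factors (9 and 13 of 32), survival genes (5 and 7 of 21), amino acid transport and endoplasmic reticulum stress (6 and 4 of 19) and genes raised by histone deacetylase inhibitors (2 and 8 of 15). Adjusted over the list alone these counts were the same, except for 4 falls among costimulatory receptors and 14 among fate transcription factors.

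Most markers of other cells stood higher on the naive arrays. The haemoglobin gene Hba-a1 fell by 4.65 ± 0.32 and the immunoglobulin light chain segment Igkv6-23 by 5.04 ± 0.76 on the log2 scale. Of 9 myeloid and dendritic cell markers 8 fell, with C1qb going from a mean log2 value of 10.42 (9.55, 11.59 and 10.11 on naive replicates 1, 2 and 3) to 7.12. Also lower were 3 of 3 NK cell markers, 2 of 2 CD4 and gamma-delta T cell markers, 3 of 3 stromal markers, 1 of 2 erythroid and platelet markers, and 5 of 9 B cell markers, with 1 B cell marker, the class II gene H2-Ab1, higher. Among 12 CD8 T cell identity genes 2 rose and 4 fell, with Cd8a at 13.36 on naive and 13.41 on Ag-B7 arrays. Of 7 reference genes 3 rose and 2 fell, with Actb lower (13.11 to 11.19) and Hprt higher (11.98 to 13.69). Naive replicate 2 had the highest naive value for 19 of the 28 markers of other cells and the lowest for 9 of the 12 CD8 T cell identity genes. Without it, a fit chosen after seeing the data, 17 of the 28 fell and 1 rose, with 6 of 9 myeloid and dendritic cell markers lower, and 0 of the identity genes rose and 4 fell. Without naive replicate 3, chosen in the same way, 20 of the 28 fell and 1 rose, and 0 of the identity genes rose and 1 fell. Control probe sets without a target were higher on naive arrays too, 29 of 34, with a median log2 difference of -0.82.

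limma with Benjamini-Hochberg adjustment called 3876 of 6278 genes, 1640 higher and 2236 lower in Ag-B7 cells, and 2807 of them changed at least 2-fold. This split depended on the scaling of the arrays: it was 1934 higher and 1639 lower under quantile normalization, 2554 and 1001 under median centring, and 4038 and 56 under spike-in scaling, an alternative chosen after seeing the data. The median log2 difference over all genes was -0.23 as deposited and 0.03, 0.41 and 1.55 under these scalings, so every value above is relative to the mean signal of an array, and falls smaller than 1.78, the distance between the spiked-in controls of the groups, would be rises on the spike-in scale. Leaving out naive replicate 1 gave 3936 calls, 1699 higher and 2237 lower, leaving out naive replicate 2 gave 3504, 1482 and 2022, and leaving out naive replicate 3 gave 3571, 1561 and 2010.

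**Figure D1:**
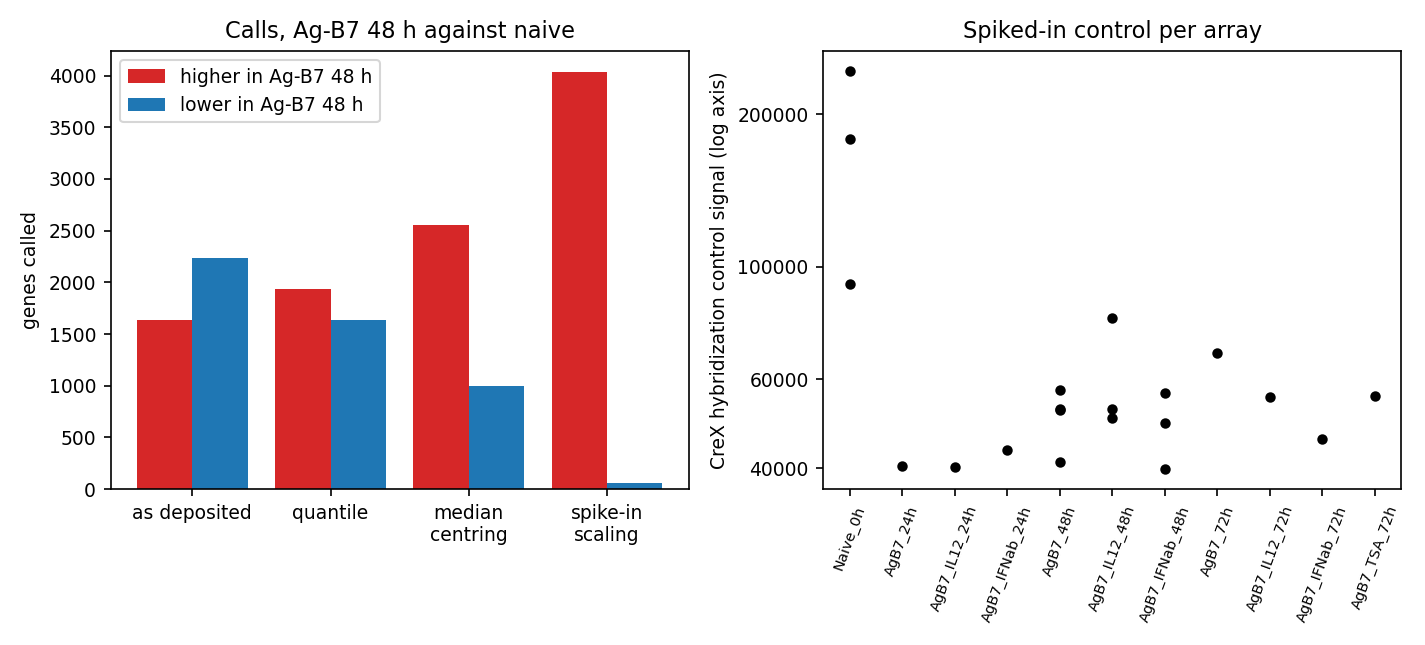
The left panel gives the number of genes called higher (red bars) and lower (blue bars) in Ag-B7 cells at 48 h than in naive cells, as deposited and under 3 other scalings; the balance turned from 1640 higher and 2236 lower to 4038 and 56 under spike-in scaling. The right panel gives the CreX spiked-in control signal of each of the 20 arrays (points, log axis) by group, with naive arrays at 92453 to 243826 and stimulated arrays at 39860 to 79260.

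Adding IL-12 to Ag-B7 raised Ifng, the gene of the effector cytokine interferon-gamma, 17.8-fold at 48 h (log2 difference 4.16 ± 0.49, n = 3 and 4, limma adjusted p = 0.000243). Usp18, an interferon-induced protease and inhibitor of type I interferon receptor signalling, rose 18.4-fold (4.20 ± 0.41). Il18r1, a chain of the receptor for IL-18, rose 4.50-fold, the death ligand Fasl 3.17-fold and Serpinb9, an inhibitor of granzyme B, 3.31-fold with overlapping arrays. Some interferon-inducible genes fell: the GTPase Iigp1 7.74-fold (-2.95 ± 0.38, limma adjusted p = 0.000501), the GTPase Ifi47 2.63-fold and the secreted glycoprotein Lgals3bp 2.27-fold.

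The further rises by the naming rule were those of the protease inhibitor Ctla2b (3.95 ± 0.69), the prion protein gene Prnp (3.15 ± 0.36), the homeodomain protein Hopx (2.47 ± 0.24), the retinoic acid carrier Crabp2 (2.38 ± 0.39), the GTPase Gem (2.13 ± 0.32), the membrane protein Emp1 (1.99 ± 0.35) and the proprotein convertase Furin (1.99 ± 0.19). Gadd45g, a stress-signalling protein linked to interferon-gamma production, rose by 1.96 ± 0.34. The further falls were those of the epoxide hydrolase Ephx1 (-2.11 ± 0.43), the G protein regulator Rgs10 (-1.53 ± 0.18), the IL-6 receptor chain Il6ra (-1.53 ± 0.30), the lysosomal protease Ctss (-1.45 ± 0.25), the membrane protein Itm2a (-1.30 ± 0.25), Slfn1 (-1.21 ± 0.26), the diacylglycerol kinase Dgka (-1.12 ± 0.21), the actin-capping protein Capg (-1.06 ± 0.18), Pdlim1 (-1.04 ± 0.20) and the transcription factor Nfatc1 (-1.01 ± 0.21). Ctss is also the only marker of myeloid and dendritic cells called here; no other member of the 8 marker lists was called. Dimmer probe sets showed almost no difference for Capg (0.003 and -0.005) and Pdlim1 (0.051). For Rgs10 a dimmer probe set had the opposite sign, while another differed by -1.08, and Crabp2 had a low value on Ag-B7 replicate 2.

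Several genes chosen in advance were not called in the fit without pairing. Their log2 differences were 2.09 ± 0.50 for Bcl3 (limma adjusted p = 0.0753), 1.41 ± 0.37 for Prf1, 1.38 ± 0.46 for Il12rb2, 1.09 ± 0.43 for Il2ra, 0.93 ± 0.27 for Gzmb (limma adjusted p = 0.207), 0.65 ± 0.52 for Eomes and -0.27 ± 0.30 for Stat4. With the replicate number as a block, limma called Il12rb2 (1.62, adjusted p = 0.00171), Bcl3 (2.11, adjusted p = 0.0322) and Gzmb (0.94, adjusted p = 0.0457). That fit also called the cell cycle inhibitor Cdkn1a (1.49, adjusted p = 0.00540), the metallothionein Mt1 (1.12), the peptide-loading protein Tapbp (-0.84) and the homing receptor Ccr7 (-1.27), and lost Lgals3bp (-1.03, limma adjusted p = 0.0553).

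Of 17 IL-12 and STAT4 associated genes 5 rose and 0 fell over all genes, and 12 rose adjusted over the list alone, with a median of 1.38 (camera in limma, adjusted p = 1.8e-21, and 0.000445 with an estimated correlation). Of 14 cytotoxic effector molecules 2 rose, Serpinb9 and Fasl, and 6 rose adjusted over the list alone (camera in limma, adjusted p = 1.07e-07, and 0.0125 with an estimated correlation). Of 31 interferon-stimulated antiviral genes 3 fell and 1, Usp18, rose, and 9 fell and 1 rose adjusted over the list alone, with a median of -0.41 (camera in limma, adjusted p = 3.0e-08, and 0.0340 with an estimated correlation). The fry test (limma) called the 3 lists in the same directions (adjusted p = 9.92e-05, 0.0136 and 0.0339). All 3 lists kept these directions under quantile normalization, median centring and spike-in scaling.

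Preset camera (limma) called 7 more lists. Naive T cell and quiescence genes were placed lower, with 3 falls and 0 rises among 25, and 6 falls and 2 rises adjusted over the list alone, and the 13 MHC class I genes were placed lower with 0 called. Their calls were lost, with adjusted p = 0.212 and 0.250 with an estimated correlation. Cytokine receptors and JAK-STAT components (1 rise, Il18r1, and 1 fall, Il6ra, of 31, and 5 rises and 1 fall adjusted over the list alone), survival genes (1 rise, Fasl, of 21, and 2 over the list alone), ribosome biogenesis, amino acid transport, and genes raised by histone deacetylase inhibitors (0 called members in each of the last 3, and 0, 0 and 3 rises over the list alone) were placed higher. Their adjusted p = 0.306, 0.256, 0.459, 0.250 and 0.0776 with an estimated correlation. Fate transcription factors gave 1 fall of 32, Nfatc1, with 3 rises and 4 falls adjusted over the list alone, and homing receptors, costimulatory receptors, chromatin modifiers, cell cycle, glycolysis and immediate early genes gave 0 called members (1 rise for chromatin modifiers over the list alone), none of these lists being called. Cytokines and chemokines gave 1 rise of 14, Ifng, by either count, with a median of -0.08 beside an upward camera direction that was not called. With the replicate block, camera (limma) at the preset correlation also called fate transcription factors, glycolysis, and immediate early and heat shock genes upward and cell cycle genes downward (adjusted p = 0.0194, 0.0301, 0.0137 and 0.0221). The block was not tested with an estimated correlation. Without the block these lists had camera adjusted p = 0.625, 0.459, 0.511 and 0.459 with an estimated correlation.

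limma with Benjamini-Hochberg adjustment called 39 genes, 24 higher and 15 lower with IL-12, and 38 of them changed at least 2-fold. With the replicate number as a block, which was taken to pair these arrays, it called 81 genes, 46 higher and 35 lower, including 34 of the 39. That fit held the 48 h arrays alone, which gave 52 genes without the block, so leaving out the naive arrays is part of the rise. Median centring gave 17 higher and 6 lower, and a fit without the intensity trend 18 and 7. Spike-in scaling, chosen after seeing the data, gave 5 higher and 2 lower. The count was 19, 25, 22 and 31 without Ag-B7 replicates 1, 2, 3 and 4 and 16, 22 and 17 without IL-12 replicates 1, 2 and 3. Usp18, Ifng, Prnp, Hopx, Gem, Furin, Iigp1 and Rgs10 were called in each of these 7 fits; Crabp2, Emp1, Gadd45g, Ctss and Capg lost their call in 1, Ctla2b in 2, Il18r1 and Ifi47 in 3, and the other named genes in 5 to 7 of them. The limma adjusted p of Il18r1 was 0.0832, 0.0509 and 0.0660 without IL-12 replicates 1, 2 and 3. Without IL-12 replicate 1 it was 0.166 for Fasl, 0.221 for Serpinb9, 0.0748 for Crabp2, 0.0968 for Gadd45g and Ctla2b, 0.0832 for Capg and 0.106 for Lgals3bp (limma). Without IL-12 replicate 3 it was 0.195 for Fasl, 0.185 for Serpinb9, 0.0516 for Ctla2b and 0.0674 for Ctss, and without IL-12 replicate 2 it was 0.0565 for Emp1 and 0.0951 for Ifi47 (limma). Under quantile normalization Ephx1, Itm2a, Nfatc1 and Slfn1 were not called.

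Adding IFNa/b to Ag-B7 raised 15 of the 31 interferon-stimulated antiviral genes tested. Usp18 rose 70.9-fold (log2 difference 6.15 ± 0.41, n = 3 and 4, limma adjusted p = 3.2e-07), and Isg15, an interferon-induced ubiquitin-like modifier, 29.4-fold (4.88 ± 0.41). The antiviral exonuclease gene Isg20 rose 15.0-fold, the membrane restriction factor Ifitm3 11.7-fold, the antiviral enzyme Rsad2 10.3-fold and the transcription factor Irf7 7.46-fold. Another, dimmer probe set of Irf7 differed by 0.92 on the log2 scale and was not called. Ifng rose 5.57-fold (2.48 ± 0.49, limma adjusted p = 0.0278).

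The other rises by the naming rule were those of Gm9706, an Isg15-like gene (5.02 ± 0.47), the ubiquitin ligase family member Trim30a (2.14 ± 0.26, with another, dimmer probe set showing no difference) and the RNA sensor Ifih1 (2.08 ± 0.27). Serpinb9 rose by 1.84 ± 0.35 and Slfn1, a growth-regulating gene of the naive list, by 1.42 ± 0.26. Genes chosen in advance and not called were Eomes (1.53 ± 0.52), Fasl (1.17 ± 0.33), Prf1 (1.00 ± 0.37), Il12rb2 (1.00 ± 0.46), Gzmb (0.97 ± 0.27, limma adjusted p = 0.234), Il2ra (0.52 ± 0.43), Bcl3 (0.46 ± 0.50) and Stat4 (0.09 ± 0.30). None of the genes of the 8 marker lists was called.

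Of 31 interferon-stimulated antiviral genes 15 rose and 0 fell, and 25 rose adjusted over the list alone, with a median of 1.32 (camera in limma, adjusted p = 2.61e-72, and 2.49e-05 with an estimated correlation). The IL-12 and STAT4 associated genes were placed higher, with 1 rise, Ifng, of 17 and 3 adjusted over the list alone (camera in limma, adjusted p = 1.03e-05, and 0.0359 with an estimated correlation), but fry did not call them (adjusted p = 0.0557). Both directions held under quantile normalization, median centring and spike-in scaling. Preset camera (limma) called 9 further lists that were lost with an estimated correlation. Placed higher were MHC class I presentation (0 of 13 called, 2 adjusted over the list alone, adjusted p = 0.111 with an estimated correlation) and amino acid transport and endoplasmic reticulum stress (0 of 19 called, adjusted p = 0.0762 with an estimated correlation). Cytotoxic molecules, with Serpinb9 called and 4 rises and 1 fall adjusted over the list alone, and cytokines and chemokines, with Ifng called and 2 rises and 1 fall over the list alone, were placed higher too (adjusted p = 0.246 and 0.209 with an estimated correlation), as were ribosome biogenesis, survival and immediate early genes with 0 called members (adjusted p = 0.246, 0.257 and 0.341 with an estimated correlation). Placed lower were cell cycle genes with 0 called members and naive T cell genes, in which Slfn1 was called higher and 1 rose and 3 fell adjusted over the list alone (adjusted p = 0.247 and 0.341 with an estimated correlation). The other 7 lists were not called and had 0 called members, with 1 rise over the list alone among cytokine receptors and JAK-STAT components.

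limma with Benjamini-Hochberg adjustment called 27 genes, 26 higher and 1 lower with IFNa/b; the lower one was Tmem71, which falls outside the naming rule and was looked up after the count was seen. The count was 15 without IFNa/b replicate 1 and 14 without IFNa/b replicate 2. The call of Ifng was lost in 6 of 7 fits that each left out an array (limma adjusted p = 0.0590, 0.107 and 0.0546 without Ag-B7 replicates 1, 2 and 3, and 0.193, 0.0703 and 0.170 without IFNa/b replicates 1, 2 and 3). Serpinb9 was lost in 6 of them (highest limma adjusted p 0.166, without IFNa/b replicate 2) and Slfn1 in 4 (0.138 without IFNa/b replicate 1, and 0.0596 under quantile normalization), and the other 9 named genes were called in each.

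Compared directly at 48 h, cells given IL-12 had far lower interferon-stimulated transcripts than cells given IFNa/b. Isg15 was 82.1-fold lower (log2 difference -6.36 ± 0.44, n = 3 and 3, limma adjusted p = 4.14e-07), Isg20 35.6-fold and Rsad2 13.7-fold lower, and Iigp1 differed by -4.39 ± 0.40. Ctla2b was 15.2-fold higher with IL-12, Prnp 12.2-fold, the calcium-binding protein S100a6 10.5-fold and Il18r1 5.90-fold. None of the effector genes chosen in advance was called between the cytokines in the main fit. The difference was 1.68 ± 0.53 for Ifng (limma adjusted p = 0.306), 0.49 ± 0.35 for Fasl, 0.41 ± 0.40 for Prf1 and -0.04 ± 0.28 for Gzmb. The Ifng arrays did not overlap, at log2 values of 12.60 to 13.02 with IL-12 and 10.59 to 11.45 with IFNa/b. Its error pools all replicated groups, and the Ag-B7 arrays ran from 7.20 to 10.25. With the replicate number as a block and the 48 h arrays alone, Ifng was called, so a difference in Ifng is not excluded.

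The other genes higher with IL-12 by the naming rule were the galectin Lgals3 (2.47 ± 0.42), Hopx (2.30 ± 0.25), Emp1 (2.26 ± 0.37), Crabp2 (2.22 ± 0.42), the metallothionein Mt2 (1.86 ± 0.42), Gem (1.79 ± 0.34), Furin (1.76 ± 0.20) and the chromatin organiser Satb1 (1.30 ± 0.29). Those lower were Gm9706 (-5.21 ± 0.50), Ifi27l2a (-3.27 ± 0.48), Trim30a (-2.87 ± 0.27), Ifih1 (-2.73 ± 0.29), Ifi27 (-2.67 ± 0.38), Slfn1 (-2.62 ± 0.28) and Slfn2 (-1.60 ± 0.31). The myeloid marker Ctss (-1.55 ± 0.27) was lower with IL-12, and no other member of the marker lists was called. Bcl3 (1.63 ± 0.53), Il2ra (0.57 ± 0.46), Il12rb2 (0.38 ± 0.50), Stat4 (-0.36 ± 0.32) and Eomes (-0.87 ± 0.55) were not called.

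Of 31 interferon-stimulated antiviral genes 24 were lower and 0 higher with IL-12, 27 adjusted over the list alone, with a median of -1.93 (camera in limma, adjusted p = 2.6e-86, and 1.14e-05 with an estimated correlation). In MHC class I presentation Tapbp (-1.48 ± 0.24) and the peptide transporter Tap1 (-1.04 ± 0.18) were lower, 2 of 13 genes and 5 adjusted over the list alone (camera in limma, adjusted p = 2.98e-08, and 0.0273 with an estimated correlation). IL-12 and STAT4 associated genes were higher, 2 of 17 and 4 adjusted over the list alone (adjusted p = 0.0102 with an estimated correlation), as were genes raised by histone deacetylase inhibitors, 1 of 15, Mt2, and 3 adjusted over the list alone (adjusted p = 0.0389 with an estimated correlation). These 4 directions held under quantile normalization, median centring and spike-in scaling. Cytotoxic molecules were called by preset camera (limma, adjusted p = 0.00377) with 0 members called and 2 adjusted over the list alone, and lost (adjusted p = 0.0963 with an estimated correlation). The other 13 lists were not called. Over all genes and over the list alone, naive T cell genes had 1 higher and 2 lower, then 2 and 5, fate transcription factors 1 and 0, then 2 and 1, cytokine receptors 1 and 0, then 1 and 2, and immediate early genes 0 and 0, then 0 and 1. limma with Benjamini-Hochberg adjustment called 59 genes, 18 higher and 41 lower with IL-12. Among named genes, Satb1 lost its call in 5, Mt2 in 4, Crabp2, Gem and Slfn2 in 2 and Ctla2b in 1 of 6 fits that each left out an array, and the other 19 were called in each. Without IL-12 replicate 1 the limma adjusted p was 0.257 for Satb1, 0.342 for Mt2, 0.0831 for Crabp2 and 0.0794 for Ctla2b. It was 0.0893 for Gem without IL-12 replicate 3 and 0.0788 for Slfn2 without IL-12 replicate 2, and 0.0872 for Mt2 under quantile normalization (limma).

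The IL-12 and IFNa/b calls shared 6 genes that rose with both: Usp18, Ifng, Ifitm3, Serpinb9, Gpr65 and Plac8, the last 2 named only because they are in the overlap. Ifitm3 rose by 1.80 with IL-12 and 3.55 with IFNa/b, Gpr65, a proton-sensing receptor, by 1.70 and 1.41, on the log2 scale, and Plac8 2.29-fold and 2.38-fold. Slfn1 and Lgals3bp went in opposite directions, lower with IL-12 and higher with IFNa/b. No gene fell with both. The overlap was 1 gene under median centring and 4 under quantile normalization, and the IFNa/b calls of Ifng and Serpinb9 were each lost in 6 of 7 fits that left out an array. Independent lists of these sizes would share 0.0994 risers. Simulated unchanged groups against the same controls shared 0. Groups simulated without change leave few genes to call, so that count cannot show how many shared calls the common controls add. With the 4 control arrays split between the comparisons, 6 fits gave 1 to 2 shared risers. The covariance of the effects across all genes was 0.0477 against 0.0448 in the simulations, a difference of 0.00288, and with split controls it was -0.0108 to 0.0202. Across genes the correlation was 0.346, below the 0.429 of the simulations, and genes are not independent replicates.

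**Figure D2:**
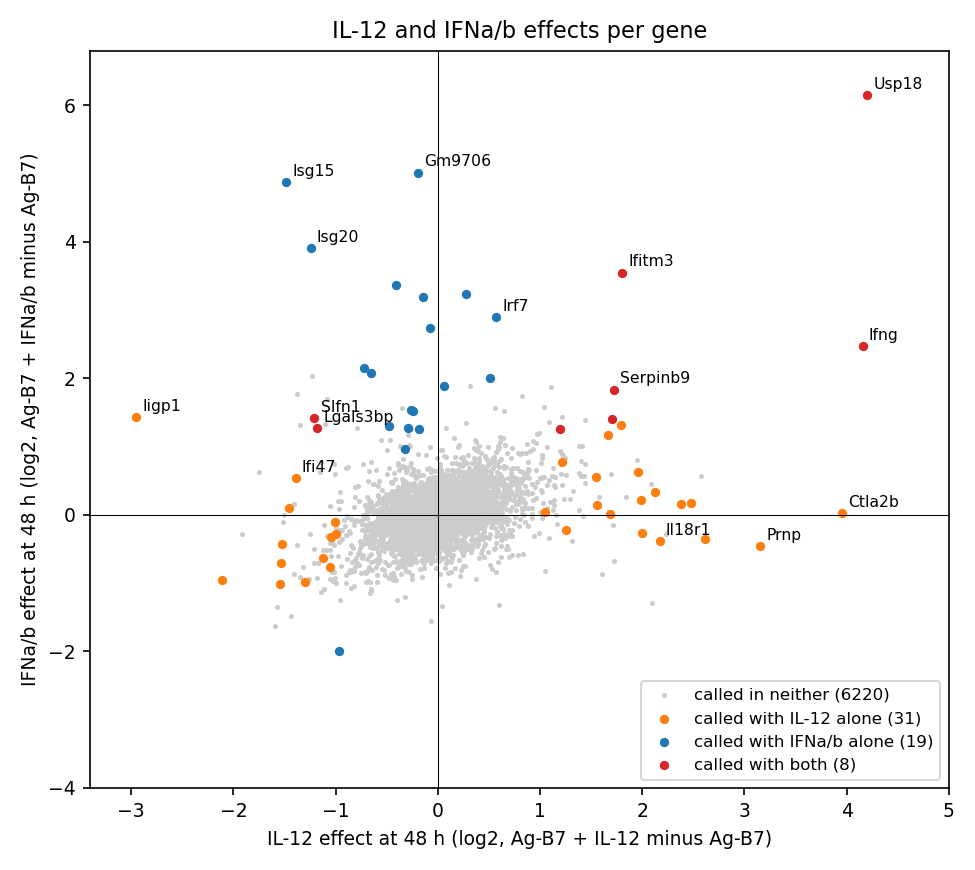
Each point is 1 of 6278 genes, with its log2 difference from Ag-B7 alone with IL-12 (x axis) and with IFNa/b (y axis) at 48 h, coloured by whether limma called it with IL-12 alone (31 genes), IFNa/b alone (19), both (8) or neither. Usp18 and Ifng lie at the upper right, Isg15 and Isg20 are high with IFNa/b and below 0 with IL-12, and Prnp and Ctla2b are high with IL-12 alone.

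On the single arrays of 24 h, Ifng was the gene with the largest difference with IL-12 (17.8-fold higher than with Ag-B7 alone, a log2 difference of 4.15), followed by Bcl3 (3.14), the inhibitory receptor gene Lilr4b (2.91), Il18r1 (2.54) and Gadd45g (2.52). With IFNa/b at 24 h the leading genes were Usp18 (59.7-fold), Gm9706 (37.4-fold), Isg15 (27.9-fold), Ifi27l2a (13.6-fold) and Ifit1 (10.5-fold). At 72 h with IL-12 the metallothionein Mt1 (12.9-fold), Ifng (12.6-fold), the junction protein Pkp2 (10.8-fold), Bhlhe40 (10.0-fold) and Emp1 (9.33-fold) led. With IFNa/b at 72 h Usp18 (31.9-fold), Gm9706 (18.1-fold), Isg15 (14.8-fold), Ifit3 (14.6-fold) and Ifit1 (11.2-fold) led, and Ifng stood at 0.56 on the log2 scale. Usp18 with IL-12 was at 2.02 at 24 h and 2.03 at 72 h.

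The genes lowest against Ag-B7 alone at 24 h were the transcription factor Scx (-3.06), Ube2h (-2.33), Sema6c (-1.71), Nsg2 (-1.63) and Isg20 (-1.61) with IL-12, and Scx (-2.75), Ighv3-6 (-1.97), Lgi4 (-1.77), Phf7 (-1.75) and Kifc3 (-1.68) with IFNa/b. At 72 h they were Klf2 (-3.18), Iigp1 (-2.88), Nsg2 (-2.75), the interferon-induced kinase Cmpk2 (-2.74) and Tspan32 (-2.62) with IL-12. With IFNa/b at 72 h they were the lipocalin Lcn4 (-4.38), Il6ra (-2.33), Krt1 (-2.32), the metabolic regulator Txnip (-2.25) and Cd7 (-2.24). Gzmb differed from Ag-B7 alone by 0.69 and 1.81 with IL-12 and by 0.87 and 1.65 with IFNa/b at 24 h and 72 h.

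Most genes called at 48 h had the same direction on these arrays, which took no part in the calls. Of the 24 genes raised by IL-12, 21 were higher at 24 h (median 0.59) and 23 at 72 h (median 1.90), and both medians were at the 100th percentile of matched random lists. Of the 15 lowered genes 14 were lower at 24 h (median -0.49) and 14 at 72 h (median -1.49), both at percentile 0. With IFNa/b their median was -0.016 at 24 h (percentile 41.9) and -0.34 at 72 h (percentile 0.5). At each time both cytokines share the control array. Of the 26 genes raised by IFNa/b, 26 were higher with IFNa/b at 24 h (median 1.46) and 26 at 72 h (median 1.78). With IL-12 12 of these 26 were higher at 24 h, with a median of -0.027 at percentile 20.5, and 7 at 72 h, with a median of -0.61 at percentile 0. Counts of genes at least 2-fold apart did not separate most of these arrays from replicate spread: 89 and 84 genes at 24 h and 438 and 326 at 72 h, with IL-12 and IFNa/b, against 147 to 409 between replicate arrays at 48 h and 382 to 1683 between naive arrays.

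**Figure D3:**
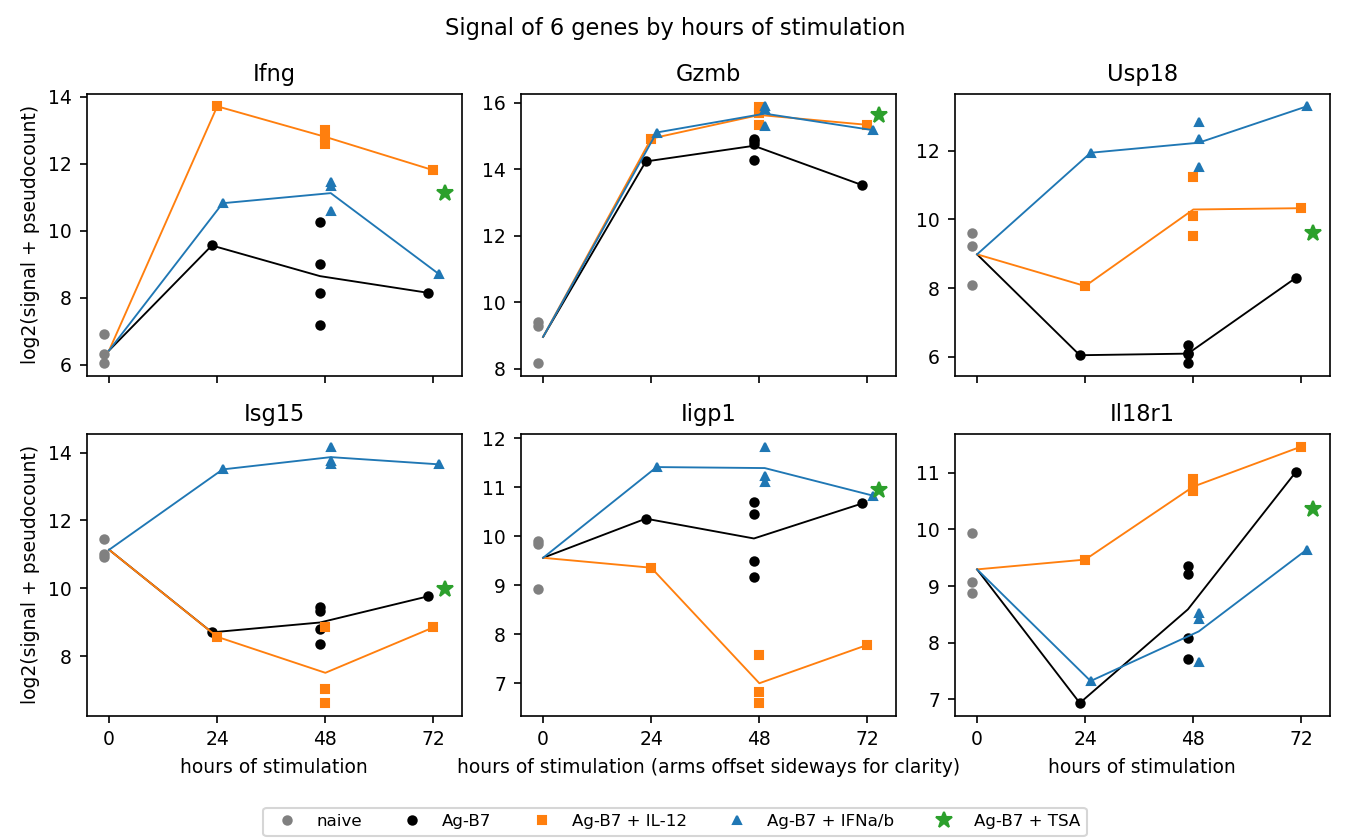
Points are single arrays of 6 genes, as log2 of signal plus pseudocount, by hours of stimulation, with lines joining group means; all arms start from the 3 naive arrays. Ifng peaks at 24 h with IL-12, Isg15 lies above 13 with IFNa/b at every time, and Iigp1 with IL-12 lies below Ag-B7 alone at 24, 48 and 72 h.

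**Figure D4:**
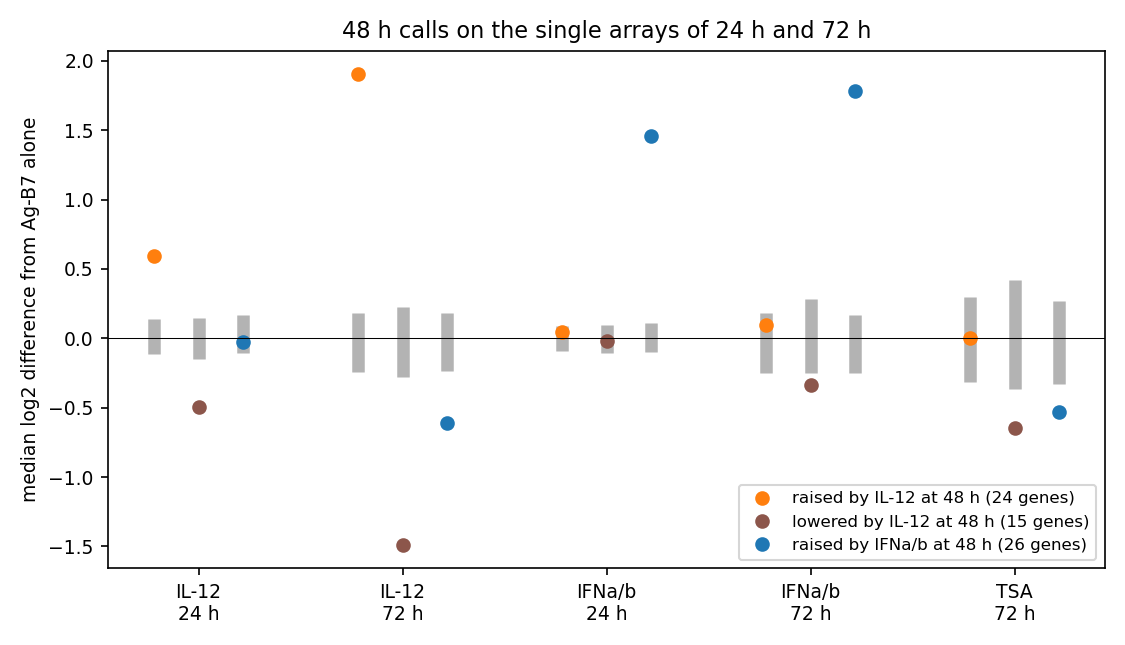
Points are the median log2 differences from Ag-B7 alone of 24 genes raised by IL-12, 15 lowered by IL-12 and 26 raised by IFNa/b at 48 h, on the single arrays of 24 h and 72 h; grey bars hold the central 95% of medians of 10000 matched random lists. IL-12 genes lie outside the bars with IL-12 at both times, and with TSA the genes raised by IL-12 lie at 0.00.

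With TSA at 72 h some effector cytokine genes were higher than with Ag-B7 alone. The cytokine Tnf was 14.7-fold higher, the transcription factor Eomes 14.2-fold, the chemokine Ccl4 11.3-fold, Crabp2 17.8-fold and Scx 15.3-fold. Klf2 was 18.5-fold lower, the glycolytic enzyme Aldoc 12.7-fold, Lgals3 9.92-fold, the chemokine receptor Cxcr4 8.93-fold and the purine enzyme Xdh 8.37-fold lower. Genes compared with IL-12 at 72 h were chosen after their values were seen, and both differences share the control array. Klf2, Ifng, Crabp2 and Gadd45g differed in the same direction with TSA (-4.21, 2.97, 4.15 and 3.31) and with IL-12 (-3.18, 3.66, 2.63 and 2.47), while Lgals3, Aldoc and Emp1 differed in opposite directions (-3.31, -3.67 and -0.24 with TSA, 1.64, 2.35 and 3.22 with IL-12). Il2ra differed by 2.12, Gzmb by 2.09, Bcl3 by 0.65, Prf1 by 0.26, Il12rb2 by 0.07, Fasl by -0.47 and Stat4 by -1.49 on the log2 scale.

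The genes raised by IL-12 at 48 h had a median TSA difference of 0.00 (percentile 48.2, 12 of 24 higher), and those raised by IFNa/b -0.53 (percentile 0.15, 9 of 26 higher). The genes lowered by IL-12 had a median of -0.65 with TSA (percentile 0.09, 11 of 15 lower). TSA gave 835 genes at least 2-fold apart, 377 higher and 458 lower, above the 147 to 409 between replicate arrays at 48 h but within the 382 to 1683 between naive arrays. The 72 h differences share 1 control array. Noise simulated with the spread of the 48 h arrays would give a covariance of 0.140 through that array. The spread at 72 h cannot be measured with 1 array per group, so the true value may differ. The covariance across genes was 0.142 for TSA and IL-12, 0.140 for TSA and IFNa/b and 0.186 for IL-12 and IFNa/b. Against the 48 h effects, with no array in common, the TSA differences correlated across genes at 0.133 for IL-12 and 0.134 for IFNa/b, and genes are not independent replicates.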

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

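The tests of spiked-in controls, of the yeast and bacterial controls, of Isg15, of the interferon-gamma receptor genes, of red cells and of B cells were chosen only after the results were seen, while the first background tests, the ranks at 24 h and 72 h and the splits of the arrays were set before.

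Among Ag-B7 arrays at 48 h a single array lay far from the others for Crabp2 (6.37 on replicate 2), Il7r (9.49 on replicate 2) and Vps37b (8.22 on replicate 3), as log2 values, which is 3 of 110 values tested where chance alone gives about 1 in 20. Some genes called with IL-12 at 48 h had the opposite sign on a single array at another time, a difference that was not tested. Capg stood at 0.45 at 72 h, and at 24 h Tmc6 stood at 0.15, H2-Q10 at -0.052, Fah at -0.35 and Mmp10 at -0.11. Prl stood at -0.63 at 72 h. Among 933 probe sets not named for 1 gene, 12 were called with IL-12 (8 higher and 4 lower) and 2 with IFNa/b (2 higher).

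More genes were called lower (2236) than higher (1640) in Ag-B7 cells than in naive cells. Of the 35 splits of these 7 arrays, 1, the real one, gave as many calls as 3876, with 2415 in the highest other split. If the arrays are exchangeable, this argues against chance in their grouping for the total count. The splits counted calls of either direction, so they do not bear on the excess of lower calls. The 9 hybridization control probe sets were 1.78 higher on the log2 scale on naive than on Ag-B7 arrays, with the lowest naive array at 13.4 and the highest Ag-B7 array at 12.7, which is consistent with less labelled RNA on the naive arrays per spiked-in control. Whether naive cells held less RNA, as a biological difference, or less of it was labelled was not tested. A background raised on the naive arrays by the scaling cannot be told apart from it, because the control sets gave opposite answers: 100% of 836 dim and 61.9% of 1400 bright genes called lower lost no more signal than the 95th percentile of 34 control probe sets (1491), but 0.239% and 0% lost no more than that of the 19 yeast and bacterial ones (133). The first bound came from antisense probe sets to abundant targets, and no dim gene had a naive mean above 966, so the test on dim genes could not have come out otherwise.

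Of 31 interferon-stimulated genes 3 fell with IL-12, 1, Usp18, rose and 27 were not called, with a median of -0.41 and 9 differences above 0, while Ifng and the interferon-induced Ifitm3 (1.80), which are not on that list, rose. IFNa/b in the IL-12 cultures, or arrays exchanged with those of IFNa/b, would have raised Isg15, which differed by -1.48 (SE 0.41) from Ag-B7 alone. On the single arrays the median of the list was at percentile 0 of random lists at both 24 h and 72 h, also without Usp18. Each time has 1 array per group and genes are not independent replicates, so these ranks cannot decide on chance between cultures. At 72 h the list was also low with TSA against the same control array (median -0.52, percentile 0.02). Lower transcripts of the interferon-gamma receptor stay open, since Ifngr1 differed by 0.08 ± 0.30 and Ifngr2 by -0.35 ± 0.40 (limma adjusted p = 0.998 for both). Inhibition of type I interferon receptor signalling by Usp18 may be a biological candidate, a hypothesis that no group of this design tests.

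Red cell and immunoglobulin transcripts were higher on the naive arrays. The smaller of the falls of 2 haemoglobin genes was -3.70, that of Hbb-b2, from a mean log2 value of 9.70 to 6.00, and Hba-a1 went from 13.03 to 8.38, which is consistent with red cells in the naive preparations, although these were CD8 cells kept by negative enrichment. By the genes tested, B cells cannot be told apart from other sources. Cd79a fell (-1.67) and Cd74 (-0.56) and H2-Eb1 (-0.78) were not called, while H2-Ab1 was higher after activation by 2.38. Among the B cell markers outside that test, mean log2 values went lower for Ms4a1 (9.57 to 7.89), Pax5 (9.88 to 8.23), Blk (8.98 to 7.63) and Ighm (13.47 to 12.74). Cd79b went from 8.19 to 8.32. No biological explanation was tested.

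For IFNa/b, 1 of 35 splits gave as many calls as the real 27, with 18 in the highest other split. These splits treat the arrays as exchangeable. Ag-B7 replicates 2 and 3, however, correlated at 0.283 and 0.278 with an IFNa/b array of another number. Chance in the grouping of arrays is therefore not excluded. For IL-12, 1 of the 35 splits of its 7 arrays gave as many as the real 39. The replicate numbers were taken to pair these arrays, however, and then only the 8 splits that part all 3 pairs compare with the real one. These are too few for a share under 0.05; the highest other among them gave 7, and the 27 splits that part fewer pairs gave at most 3. For IL-12 against IFNa/b the 10 splits are too few for a share under 0.05; 1 gave as many calls as the real 59, and the highest other gave 0.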

How the results depend on the processing

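Spike-in scaling, fits of the 48 h arrays alone and the block within the IL-12 and Ag-B7 arrays alone were chosen after the results were seen. Of the named genes that were called, 0 reversed when arrays were left out, under quantile normalization, under other pseudocounts or with the replicate block. For most of these genes the arrays of the compared groups did not overlap. Leaving out an array or changing the pseudocount could not reverse the sign of such a gene, so those settings did not test its direction. With arrays left out, calls held in 529 of 532 values for activation, 113 of 182 for IL-12, 68 of 84 for IFNa/b and 134 of 150 for IL-12 against IFNa/b, and under quantile normalization in 74 of 76, 22 of 26, 11 of 12 and 24 of 25. For dim genes the 20th percentile of signal, 30.0 to 115 between arrays, limits what can be seen.

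The count for IL-12 was 23 under median centring, 7 under spike-in scaling, 25 without the intensity trend and 16 to 31 with arrays left out. That for IFNa/b was 15 under spike-in scaling and 14 to 32 with arrays left out, and that between the cytokines was 37 under spike-in scaling. The overlap was 1 gene under median centring. Genes raised by IL-12 shared their sign at 72 h in 100% with 4 times the pseudocount, and lowered genes at 24 h in 100% under quantile normalization and median centring. With 4 times the pseudocount, which shrinks differences of dim genes, 2-fold counts were 30 for IL-12 and 38 for IFNa/b at 24 h and 216 for IFNa/b at 72 h. With an estimated correlation camera called 1 list for activation, 3 for IL-12 and 2 for IFNa/b, and under spike-in scaling 11 for activation. Apart from the pseudocount, the cause was not tested.

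With the replicate block, IL-12 had 81 calls in the 48 h arrays, against 52 in the same arrays without it. In a fit of its own arrays and those of Ag-B7 it had 191, against 42 without the block. Beyond the changes given beside the IL-12 results, the block changed no other call of its named genes and lists. The other groups share only a number: same-numbered Ag-B7 and IFNa/b arrays correlated at 0.112, -0.0421 and -0.0965, and not every array correlated best with its own number: Ag-B7 replicates 2 and 3 reached 0.283 and 0.278 with an IFNa/b array of another number, as high as the paired IL-12 arrays. There the block gave 3708 calls for activation, 103 for IFNa/b (70 higher and 33 lower) and 113 between the cytokines. The last 2 fits held the 48 h arrays alone, which without the block gave 34 and 80 calls. Between the cytokines it also called Ifng (1.68, limma adjusted p = 0.0113).

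On other probe sets of called named genes, calls held in 10 of 20 values for activation and 1 of 6 for IL-12. They held in 0 of 2 for IFNa/b and 3 of 6 between the cytokines. Another probe set had the opposite sign for Bad (1.80), Cd44 (-0.75), Hk2 (-0.72), Lta (-2.17), Mki67 (-1.75), Mthfd2 (-0.091) and Tnfrsf9 (-1.17) in activation. With IL-12 this held for Rgs10 (0.51), although a further, brighter probe set of Rgs10 was at -1.08. Other probe sets of Capg (0.00305 and -0.00546) and Pdlim1 (0.051) showed almost no difference with IL-12. The same held for Trim30a with IFNa/b (-0.00131) and between the cytokines (0.069). The cause was not tested.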

Other observations

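The lists were fixed before the data were examined, and the genes given as examples here were chosen after their values were seen; all values are single arrays at 72 h against Ag-B7 alone unless another time is given. Glycolysis genes were higher with either cytokine at 72 h, with a median log2 difference of 1.31 and 9 of 16 genes at least 2-fold higher with IL-12, and 0.64 and 7 of 16 with IFNa/b, both at the 100th percentile of matched random lists. The cytokines share the single Ag-B7 array of 72 h, so their agreement is partly built in. Their differences correlated across genes at 0.527, against 0.499 from noise simulated with the spread of the 48 h arrays, a value fixed by the shared array. Hk2, the enzyme of the entry step of glycolysis, stood at 2.84 with IL-12 and 2.41 with IFNa/b, Tpi1 at 1.97 and 1.46 and Aldoc at 2.35 and 0.64. At 24 h the medians of this list were -0.0012 and 0.04, and with TSA at 72 h it was 0.03. Amino acid transport and endoplasmic reticulum stress genes had medians of 0.81 with IL-12 and 0.68 with IFNa/b, each with 8 of 19 genes at least 2-fold higher, including the asparagine synthetase Asns at 2.38 and 2.41. Costimulatory and inhibitory receptors had a median of 0.57 with IL-12, 0.31 with IFNa/b and -0.69 with TSA, where 6 of 18 were at least 2-fold lower. Tnfrsf9 stood at 2.70 and Tnfrsf4 at 2.55 with IL-12, and at 1.94 and 2.22 with IFNa/b.

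With TSA the cytokine and chemokine list had a median of 0.98, with 7 of 14 genes at least 2-fold higher, among them Lta at 3.36, Ccl3 at 3.12 and Xcl1 at 2.45. Ribosome biogenesis and MYC targets had a median of 0.88 with 8 of 25 at least 2-fold higher, and cell cycle genes 0.53 with 7 of 41. Naive T cell and quiescence genes had a median of -0.92 with 10 of 25 at least 2-fold lower, and interferon-stimulated genes -0.52 with 10 of 31 lower. The list of genes raised by histone deacetylase inhibitors in other cells had a TSA median of 0.11 at percentile 70.9, with 1 of 15 genes at least 2-fold higher and 1 lower. Cell cycle genes were lower with IL-12 at 72 h, with a median of -0.38 at percentile 0.01, and of -0.017 under spike-in scaling.

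With Ag-B7 alone, on single arrays at 24 h and 72 h, several lists lay nearer to naive levels at 72 h than at 24 h as deposited. Against naive cells the median of naive T cell and quiescence genes was -2.53 at 24 h, -1.90 at 48 h and -0.80 at 72 h, that of interferon-stimulated genes -1.69, -1.32 and -0.14, and that of ribosome biogenesis and MYC targets 1.53, 1.13 and -0.11. Cell cycle genes stayed high at 2.32, 2.35 and 1.68. The median of all genes was -0.33, -0.23 and -0.06 at these times. Other scalings were applied to these medians after seeing the data. Under spike-in scaling naive T cell genes went from -0.49 through -0.11 to 0.67, past naive levels, and interferon-stimulated genes from 0.35 through 0.46 to 1.33, away from them, while ribosome biogenesis genes stayed above (3.57, 2.92 and 1.36). Under quantile normalization and median centring the 3 lists were nearer to naive levels at 72 h than at 24 h.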
